A study of Mus musculus with 9 samples.

How the data were processed

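The samples were GFP-positive cells sorted by flow cytometry from the forebrains of C57Bl6DBa2 mouse embryos at embryonic day 16.5, 2 days after plasmids had been delivered in utero by electroporation at embryonic day 14.5. The labels place 9 samples in 3 groups of 3. The first group received a plasmid coding for GemC1, the second a plasmid coding for Mcidas, and the third the H2B-GFP reporter without either factor. Per the labels' protocols, 10 ng of total RNA was amplified with the SMART-Seq v4 Ultra Low Input kit, about 150 pg of the amplified cDNA went into Nextera XT libraries, and 12 libraries were pooled on a NextSeq flow cell and read for 75 bp. Only 9 libraries were analysed here, and the labels do not say which of them shared a pool. Neither kit marks the strand of the RNA.

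The deposited values are raw read counts per Ensembl gene, 1 table for each library, as the file headers and the whole-number values show. The submitters' processing notes name STAR 2.5.2b, HTSeq 0.5.3, DESeq2 1.8.1 and the mouse build mm10, with no role or order. The annotation release, the strand setting and any alignment filter behind the deposited counts are not given in the sources used here. Each table held 53379 gene identifiers, of which 53274 were matched to GENCODE M21 (build GRCm38, the assembly named mm10) for symbols, positions, GC content and exon length. The remaining 105 identifiers took at most 0.068% of any library's counts. No entries for unassigned reads were present.

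Total counts ran from 22914704 in Mcidas replicate 3 to 41163917 in GFP replicate 2. A floor of 3 counts in a library corresponded to between 0.0729 and 0.131 CPM (counts scaled to a common library total) before scaling. Floors and counting intervals (95%, exact binomial) cover counting error only, because amplified reads without molecular identifiers are not independent molecules. Nothing in the labels says whether the 3 replicates of a group came from separate litters or surgeries, so p-values measure the spread between these samples. Counts of each pair of replicates of a group differed by more than sampling noise (chi-square per degree of freedom from 14.1 to 25.8), and no library was counted as a copy of another.

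Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 19572 genes. Libraries were scaled by TMM, with factors from 0.96 to 1.035, and all 9 libraries entered a single quasi-likelihood fit (glmQLFit with robust estimation, glmQLFTest, two-sided) with group as the only term. The 3 comparisons were GemC1 against GFP, Mcidas against GFP and GemC1 against Mcidas. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are log2 values with the standard error (SE) derived from the quasi-likelihood F, and levels are CPM as mean ± SD over 3 libraries. Where the libraries of a group were all at 0, the fold is given as a lower bound against 3 counts per library.

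Before the data were examined, 31 gene lists were fixed for ciliation, the p53 response, the cell cycle, neural and non-neural cell types, stress and signalling. The sex-linked list was kept for values only, and 30 lists were tested with camera (limma 3.58.1, inter-gene correlation preset to 0.01, at least 5 tested members). Camera with an estimated correlation and fry were run beside it. Of the list members 1111 were matched and 7 were not. Gmnc (the gene symbol of GemC1) and Mcidas were left out of list tests because plasmids delivered them. List members are counted with adjustment over all genes tested and also adjusted over the list alone. Some lists share genes: 31 genes stand in more than 1 list. The rule for named genes was also fixed then. It takes Gmnc and Mcidas; the 8 called genes with the largest and the 8 with the smallest log2 fold change among those with an average log2 CPM of at least 3 (1 where too few qualified), a gene symbol that is not a placeholder or clone name and no overlap between the groups' replicates; the 4 members with the smallest adjusted p of each list called by camera; and 23 genes of ciliation, p53, the cell cycle and neural identity. Other genes are said to be chosen after their values were seen.

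Because both factors were compared with the same 3 GFP libraries, the correlation and covariance of fold changes were set beside 50 simulations of unchanged groups. These called at most 2 genes in a direction, so they give no number for the overlap of calls. The 3 GFP libraries were too few to split. Alternatives comprised DESeq2 size factors in edgeR, DESeq2 1.42.0, no or a stricter low-count filter, the replicate number as a block, a fit on only the groups compared, a fit without mitochondrial, globin and transgene counts, a 2-fold minimum and the removal of each library in turn. Leaving out those counts also takes the genes themselves, Gmnc and Mcidas among them, out of the tests. A correction of each library's trend on GC content was added after a correlation of fold changes with GC content had been seen.

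The procedures were tested on simulated counts drawn from the real means, library sizes and dispersions, with 200 genes changed. For GemC1 against GFP, on 19042 genes, edgeR recovered 20.9% of 1.5-fold, 55.2% of 2-fold and 75.8% of 4-fold changes, with 5 false calls among 106, and DESeq2 had 37 false calls among 147. For Mcidas against GFP, on 19062 genes, edgeR recovered 28.4%, 49.3% and 72.7% of these, with 6 false calls among 106. For GemC1 against Mcidas, on 19045 genes, it recovered 25.4%, 59.7% and 75.8%, with 11 false calls among 118, and DESeq2 had 26 among 147. With a GC trend put into the simulated GemC1 libraries, the GemC1 and GFP comparison had 1963 false calls, and 6 after the GC correction. Camera and fry called the list raised in the simulation and none of 29 unchanged lists. Genes were drawn independently of one another there. The simulation therefore cannot show how often camera calls unchanged lists whose members move together.

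Of 146 named genes, 48 overlap another tested gene on the chromosome, and since strand could not be used, reads of such partners cannot be told apart. Among them are Cdt1, which overlaps Gm20388 (134.7 CPM on average), and Slc24a5, which overlaps Myef2 (166.2 CPM). The annotated span of Fgfr2 overlaps 30 tested genes, the highest at 254.9 CPM. Figures were drawn with matplotlib.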

Results

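RNA was sequenced from GFP-positive cells of the embryonic mouse forebrain, labelled as neural progenitor cells, 2 days after electroporation with a plasmid for GemC1 or Mcidas or with the H2B-GFP reporter alone. GemC1 and Mcidas are geminin-related nuclear proteins that start the multiciliated cell programme, and the stated aim of the series was to learn how GemC1 triggers that fate. Its title also names a DNA damage, p53 and p21 response in ependymal cells, the ciliated cells that line the brain ventricles. Each group held 3 libraries. Total counts were 28515241, 28550907 and 30288663 in the GemC1 libraries, 34860313, 32157318 and 22914704 in the Mcidas libraries, and 34417359, 41163917 and 34756650 in the GFP libraries. The first principal component of log2 CPM (counts scaled to a common library total), with 40.6% of the variance, placed the 3 GFP libraries between 59.4 and 80.4, the GemC1 libraries between -37.7 and -28.4, and the Mcidas libraries at -6.6, -43.7 and -51.6 for replicates 1, 2 and 3. The files of the Mcidas libraries carry another year code than those of the GemC1 and GFP libraries. If that code marks a batch, the batch holds samples of 1 group only, and it and the Mcidas group cannot be told apart.

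The introduced genes were examined first. Gmnc (ENSMUSG00000068428), which encodes GemC1 and lies on chromosome 16 at 26913553 to 26991652 of mm10, was counted at 277.2 ± 48.6 CPM in the GemC1 group (SD, n = 3). It had 0 counts in each GFP library and 9, 0 and 6 counts in Mcidas replicates 1, 2 and 3. The GemC1 level was at least 3302-fold higher than in GFP against a floor of 3 counts per library. Mcidas (ENSMUSG00000074651), on chromosome 13 at 112993845 to 113000394, reached 497 ± 105 CPM in the Mcidas group and 0.67 ± 0.02 CPM in GFP. In the GemC1 group, which received no Mcidas plasmid per the labels, Mcidas stood at 70.0 ± 8.67 CPM, a log2 fold change of 6.71 ± 0.21 (SE) over GFP (edgeR quasi-likelihood test, adjusted p = 4.79e-09). Counts per gene do not separate reads of a plasmid from reads of the chromosomal gene.

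**Figure D1:**
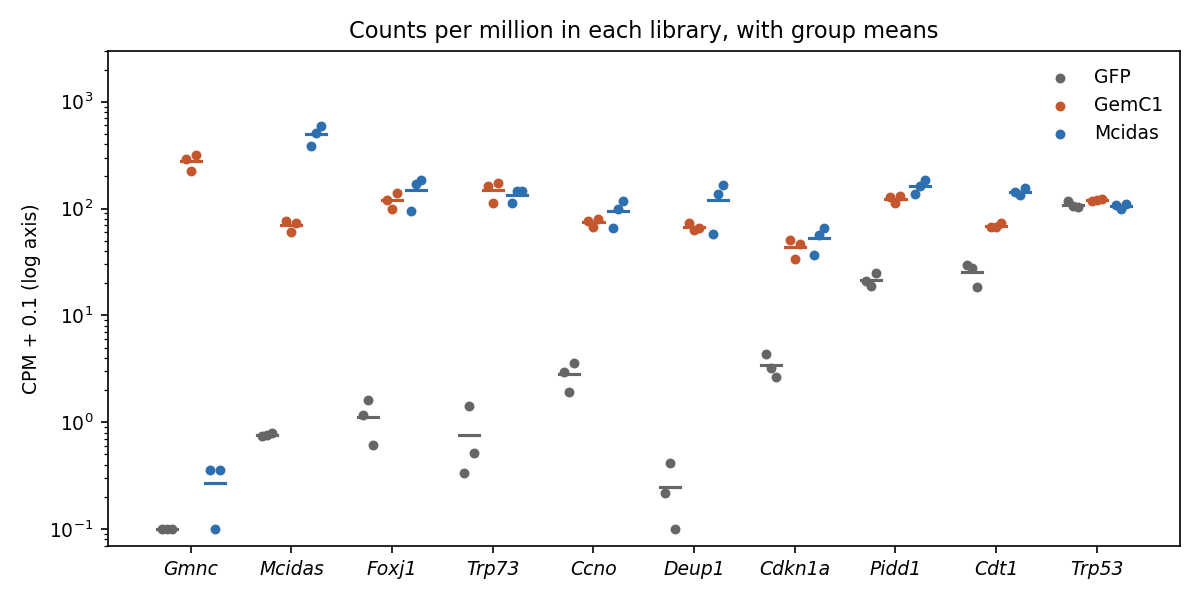
CPM of 10 genes in each library, on a log axis after adding 0.1, with points for the 3 libraries of each group and bars for group means. Mcidas lies at 70.0 CPM in the GemC1 group against 0.67 in GFP, Cdkn1a at 43.4 against 3.31, and Trp53 at 120.7 against 109.0.

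The comparison of GemC1 with GFP asked which genes the GemC1 plasmid changed. Genes of the multiciliated programme rose most. Foxj1, a forkhead factor required for motile cilia, went from 1.03 ± 0.51 to 120.1 ± 20.2 CPM, a log2 fold change of 6.83 ± 0.35 (SE, adjusted p = 1.31e-06), and Trp73, which encodes the p53 relative p73, rose by 7.74 ± 0.37 on the log2 scale (adjusted p = 1.25e-06). Within the limits of the rule for named genes, the genes with the largest changes apart from Gmnc were Wdr63, Cfap52, Cfap206, Deup1, Pifo, Crocc2 and Cfap45, most of them known parts of cilia or of the machinery that makes centrioles. Wdr63 and Cfap52 had 0 counts in GFP and were at least 181-fold and 169-fold higher. Pifo was higher by a ratio of 385 (95% counting interval 131.4 to 1871). Of 19572 genes tested, 756 were higher and 259 lower, with 531 and 40 of these changed at least 2-fold. The median log2 fold change was 2.16 among the genes that rose, and its size was 0.51 among those that fell.

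Without GFP replicate 3 the GemC1 and GFP calls dropped to 443 higher and 32 lower, and without GFP replicate 2 to 472 and 42. The lower calls numbered 162, 161 and 163 without GemC1 replicate 1, GemC1 replicate 2 and Mcidas replicate 2. DESeq2 called 1159 higher and 658 lower, and edgeR without a low-count filter called 557 lower.

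Of 115 tested members of the motile cilium axoneme list, 98 rose in GemC1 and none fell (108 adjusted over the list alone), with a median log2 fold change of 3.47. Examples were Cfap206, a radial spoke protein, at 9.19 ± 0.55 (SE) and Ccdc65, a part of the nexin-dynein regulatory complex, at 4.62 ± 0.31. Of the members, 5 were at 0 in GFP, and the median stayed at 3.47 with these at their lower bounds. Among 15 members of the multiciliated transcription list, 9 rose (9 adjusted over the list alone), including Ccno at 4.79 ± 0.25, Myb at 2.48 ± 0.15 and Rfx2 at 2.27 ± 0.29, and Rfx3 had -0.20 ± 0.10 (adjusted p = 0.31). Both lists were called by camera (adjusted p = 4.33e-184 and 1.06e-36) and with an estimated correlation (adjusted p = 0.0253 and 0.0048). Of 36 centriole genes, 9 rose (14 higher and 1 lower adjusted over the list alone). Deup1, which builds the deuterosome on which centrioles are made in multiciliated cells, rose by 8.71 ± 0.60, Cdc20b by 6.37 ± 0.42, Cep152 by 1.16 ± 0.20 and Plk4, the kinase that starts centriole duplication, by 0.61 ± 0.13 on the log2 scale. Plk4 lost its call in 3 of 18 alternatives. Among 49 genes of the primary cilium and intraflagellar transport, 18 rose (35 higher and 1 lower adjusted over the list alone), such as Tctn2 at 1.20 ± 0.18 and Ift22 at 0.98 ± 0.12. Camera called both lists (adjusted p = 1.08e-12 and 4.21e-14), and with an estimated correlation neither was called (adjusted p = 0.113 and 0.113). Fry called both (adjusted p = 0.00513 and 0.00513).

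**Figure D2:**
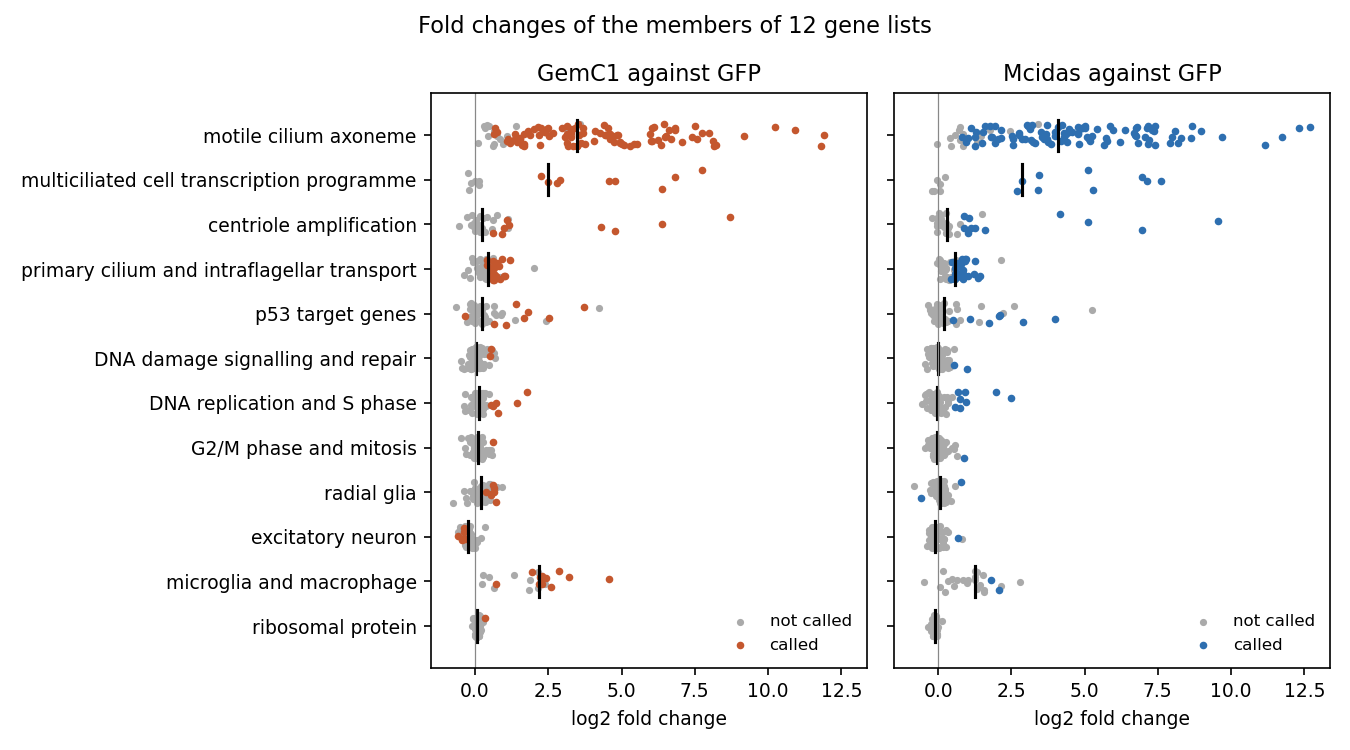
Log2 fold changes of the tested members of 12 gene lists in GemC1 and in Mcidas against GFP, with 1 point per gene (coloured where the gene was called at an adjusted p under 0.05, grey otherwise) and a black bar at the list's median. The motile cilium medians are 3.47 and 4.10, and the medians of the DNA damage signalling and repair list are 0.04 and 0.00, while points far to the right include genes at 0 in GFP, whose fitted values depend on the prior count.

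In the p53 target list, 7 of 43 tested genes rose in GemC1 and 1 fell (11 and 2 adjusted over the list alone). Cdkn1a, which encodes the cell cycle inhibitor p21 (chromosome 17, 29090976 to 29100727), went from 3.31 ± 0.84 to 43.4 ± 8.84 CPM, a log2 fold change of 3.71 ± 0.25 (SE, adjusted p = 3.18e-06). Pidd1, a p53-induced death domain protein, rose by 2.53 ± 0.13 and Eda2r by 1.66 ± 0.25 on the log2 scale, and Phlda3 rose from 2.60 ± 0.84 to 9.01 ± 3.62 CPM (adjusted p = 0.00596). Mdm2, the ubiquitin ligase that p53 induces, had -0.13 ± 0.11 (adjusted p = 0.54), Ccng1 had 0.24 ± 0.12 (adjusted p = 0.289) and Trp53 itself 0.15 ± 0.08 (adjusted p = 0.337). The gene that fell was Trp53i11, named after its values were seen, at -0.35 ± 0.08. Camera called the list (adjusted p = 1.18e-05), and so did fry (adjusted p = 0.00436), while the adjusted p with an estimated correlation was 0.096. DNA damage signalling and repair, a list of 82 tested genes, was not called (camera adjusted p = 0.361). Its 2 called members, both higher and named after their values were seen, were Lig1, a DNA ligase of replication, at 0.51 ± 0.10 and H2afx, the histone H2AX, at 0.56 ± 0.13. Telomere maintenance was not called either (adjusted p = 0.612). Its 2 called members, both lower and also named after their values were seen, were Nvl at -0.75 ± 0.12 and Atrx at -0.31 ± 0.08.

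Among 60 genes of DNA replication and S phase, 6 rose in GemC1 (8 adjusted over the list alone). They included E2f7, an E2F repressor, at 1.77 ± 0.11 (SE), Cdt1, the replication licensing factor that geminin inhibits, at 1.43 ± 0.15, Dtl at 0.78 ± 0.09 and Slbp at 0.72 ± 0.09. Geminin itself (Gmnn) had 0.19 ± 0.17 (adjusted p = 0.583) and Mcm2 0.14 ± 0.10 (adjusted p = 0.501). The list was called by camera (adjusted p = 0.000189) but had an adjusted p of 0.541 with an estimated correlation and of 0.0804 by fry. The list of G2/M phase and mitosis was not called (adjusted p = 0.151). There Mki67 had -0.17 ± 0.15 (adjusted p = 0.585) and Ccnb1 0.00 ± 0.14 (adjusted p = 1). The lists of cyclin-dependent kinase inhibitors (adjusted p = 0.343) and of apoptosis executioners (adjusted p = 0.697) were not called.

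Genes of several cell types also differed between GemC1 and GFP. Of 50 excitatory neuron genes, 7 fell and none rose (9 lower adjusted over the list alone), including Myt1l at -0.45 ± 0.09 (SE), Rbfox1 at -0.44 ± 0.11 and the migration gene Dcx at -0.37 ± 0.08. Of 45 radial glia genes, 7 rose (13 higher and 3 lower adjusted over the list alone), such as Veph1 at 0.73 ± 0.16 and Fgfr2 at 0.64 ± 0.11. Of 24 astrocyte genes, 5 rose (6 adjusted over the list alone), among them Apoe (59.9 ± 2.10 CPM, adjusted p = 0.0116), Mlc1 at 0.95 ± 0.21 and Aldoc at 0.53 ± 0.12. The last is among 4 genes that the radial glia list shares with the astrocyte list. Sox2 had 0.45 ± 0.13 (adjusted p = 0.0734), Pax6 0.26 ± 0.14, Hes5 -0.27 ± 0.14, Eomes -0.20 ± 0.14 and Tubb3 -0.16 ± 0.09, none of them called. Camera called the neuron, radial glia and astrocyte lists (adjusted p = 2.27e-08, 0.00064 and 0.000929), and with an estimated correlation none of the 3 was called (adjusted p = 0.12, 0.541 and 0.346). Fry called the neuron and astrocyte lists (adjusted p = 0.0106 and 0.0475) but not radial glia (adjusted p = 0.119). The calls of Rbfox1, Dcx, Veph1, Mlc1, Aldoc, Apoe and Myt1l were each lost in some alternatives, in 9, 6, 5, 7, 3, 2 and 3 of 18.

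Markers of microglia and macrophages, cells outside the neural lineage, moved with the GemC1 group. Of 24 tested markers, 12 rose (17 adjusted over the list alone) and all 24 had a positive log2 fold change, with a median of 2.19. Levels stayed low. P2ry12 was at 4.04 ± 1.46 CPM in GemC1 and 0.54 ± 0.39 in GFP, and C1qb at 4.64 ± 1.28 and 0.77 ± 0.20. The list was called by camera (adjusted p = 5.31e-14), and the adjusted p was 0.12 with an estimated correlation and 0.0106 by fry. Endothelial, pericyte, meningeal and erythroid lists were not called (adjusted p = 0.869, 0.437, 0.229 and 0.697). In the interferon list no member was called, though camera called the list (adjusted p = 0.0188), and with an estimated correlation the adjusted p was 0.777. That camera call was lost in 6 of 16 alternatives, with an adjusted p of 0.61 without GFP replicate 3. In the immediate early list, Egr1 rose by 0.68 ± 0.17 (SE) and Fosb by 0.94 ± 0.24 on the log2 scale, calls lost in 10 and 9 of 18 alternatives. The list (3 higher adjusted over the list alone) was called by camera (adjusted p = 0.00219), with an adjusted p of 0.435 with an estimated correlation and of 0.0595 by camera without GemC1 replicate 3. The Cajal-Retzius list rested on Trp73 and Cacna2d2, its only called members over all genes tested (2 higher and 2 lower adjusted over the list alone, the lower ones Clstn2 at -1.08 and Nhlh2 at -1.29). Its median was -0.02 and its mean 0.67, and its camera call (adjusted p = 0.0399, and 0.402 with an estimated correlation) was lost in 8 of 16 alternatives.

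Within the expression, symbol and no-overlap limits of the rule for named genes, the called genes with the smallest log2 fold changes in GemC1 were Ppp1r16b at -1.24 ± 0.17 (SE, adjusted p = 0.000832), Nyap2, Flrt3, Bhlhe22, Adamts2, Nuak1, Kcnc2 and Slc24a5. Among these, Bhlhe22 is a transcription factor of cortical neurons and Flrt3 a guidance and adhesion receptor. Their values lay between -1.24 and -0.94, and 10 other called genes, all below the expression limit, fell at least 4-fold. The calls of Slc24a5, Nyap2, Flrt3, Kcnc2, Bhlhe22, Adamts2 and Nuak1 were lost in 8, 7, 7, 7, 6, 1 and 1 of 18 alternatives. For Adamts2 and Nuak1 this was the 2-fold minimum, since their highest adjusted p over the alternatives were 0.0151 and 0.00439.

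The comparison of Mcidas with GFP asked the same of the second factor. The same families led. Foxj1 reached 149.8 ± 47.2 CPM, a log2 fold change of 7.14 ± 0.35 (SE, adjusted p = 6.96e-07), and Deup1 120.8 ± 57.1 CPM, at 9.55 ± 0.60. Cdkn1a was at 52.97 ± 14.4 CPM, a log2 fold change of 3.998 ± 0.253 (adjusted p = 1.45e-06). Of 19572 genes, 788 were higher and 64 lower, with 597 and 16 changed at least 2-fold. The largest named changes were again those of cilium genes, with Wdr63 and Cfap52 at least 310-fold and 239-fold higher than in GFP, where neither was counted. Foxj1 was at 95.8 CPM in Mcidas replicate 1 and at 170.2 and 183.3 in replicates 2 and 3, and the median motile cilium gene lay 2.85, 4.22 and 4.31 log2 units above the GFP mean in these libraries. Without Mcidas replicate 1, 951 genes were higher and 99 lower. The lower calls numbered 29 and 33 without Mcidas replicates 2 and 3, and 37, 30 and 35 without GFP replicates 1, 2 and 3. DESeq2 called 112 lower and edgeR without a low-count filter 123.

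Of the 115 motile cilium genes, 100 rose in Mcidas and none fell (111 adjusted over the list alone), with a median of 4.10, or 4.001 with the 5 members at 0 in GFP at their lower bounds. In the multiciliated transcription list 9 of 15 rose (10 adjusted over the list alone), with Ccno at 5.12 ± 0.25 (SE), Myb at 2.86 ± 0.15 and Trp73 at 7.60 ± 0.37. Of the centriole genes 11 of 36 rose (20 adjusted over the list alone), including Cdc20b at 6.95 ± 0.43, Cep152 at 1.61 ± 0.20 and Plk4 at 0.90 ± 0.13. Of the primary cilium genes 26 of 49 rose (36 adjusted over the list alone), with Ift22 at 1.43 ± 0.12 and Tctn2 at 1.35 ± 0.18. In the p53 target list 7 of 43 rose (10 adjusted over the list alone), with Pidd1 at 2.90 ± 0.14, Eda2r at 2.10 ± 0.25, Dglucy at 1.74 ± 0.26 and Ccng1 at 0.52 ± 0.12. The call of Ccng1 was lost in 5 of 18 alternatives. Mdm2 had 0.10 ± 0.11 (adjusted p = 0.797) and Trp53 -0.04 ± 0.08 (adjusted p = 0.902). Camera called these 5 lists, and with an estimated correlation all 5 were called too, with adjusted p of 0.0169 for motile cilium, 0.00341 for multiciliated transcription and 0.0354 for each of the centriole, primary cilium and p53 lists.

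DNA damage signalling and repair was not called in Mcidas (camera adjusted p = 0.81). Its 2 called members, named after their values were seen, were Lig1 at 0.996 ± 0.098 (SE) and H2afx at 0.55 ± 0.13. The telomere list (adjusted p = 0.542), G2/M phase (adjusted p = 0.64) and apoptosis executioners (adjusted p = 0.336) were not called. The S phase list was not called by camera (adjusted p = 0.0629), though 8 of its 60 members rose (9 higher and 2 lower adjusted over the list alone). Its median was -0.04 and its mean 0.09. Cdt1, named here because the other comparisons name it, rose by 2.499 ± 0.152. Neither the radial glia nor the excitatory neuron list was called (adjusted p = 0.64 and 0.118).

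Genes of the intermediate progenitors of the cortex were lower in Mcidas by camera (adjusted p = 0.000195, and 0.42 with an estimated correlation). Of 30 tested, 2 fell (1 higher and 5 lower adjusted over the list alone): Kif26b, at -1.02 ± 0.16 (SE), and Slc17a6, at -0.40 ± 0.10. The call of Slc17a6 was lost in 7 of 18 alternatives. Hes5, a Notch target of radial glia, fell by 0.59 ± 0.14 on the log2 scale (adjusted p = 0.0337), a call lost in 8 of 18. Microglia markers were higher by camera (adjusted p = 1.97e-05, and 0.436 with an estimated correlation), with 2 of 24 called (5 adjusted over the list alone). These were C1qb at 2.08 ± 0.37 and P2ry12 at 1.81 ± 0.46, the latter lost in 8 of 18 alternatives. The Cajal-Retzius list was called through the same 2 genes (adjusted p = 0.00172, and 0.203 with an estimated correlation). Immediate early genes were lower by camera (adjusted p = 0.0303, and 0.608 with an estimated correlation). Fosb, at -1.49 ± 0.26, was the member called, and the camera call was lost in 3 of 16 alternatives, without Mcidas replicate 1 (adjusted p = 0.321), without GFP replicate 1 and with a stricter low-count filter. Ribosomal protein genes were lower by camera (adjusted p = 0.000287, and 0.744 with an estimated correlation) with a median of -0.12 and no member called. The ribosomal call was lost without GFP replicate 1 (adjusted p = 0.0599).

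Most of the named genes with the smallest log2 fold changes in Mcidas encode histone H2B. Hist1h2bb, Hist1h2bm, Hist1h2bf, Hist2h2bb, Hist2h2be and Hist1h2bc had values from -1.35 ± 0.24 to -0.91 ± 0.21 (SE), with adjusted p from 0.00242 to 0.0236. Hist1h2bm, for example, was at 92.1 ± 22.5 CPM in Mcidas and at 229.7 ± 72.2 in GFP. None of these was called in GemC1 against GFP. H2B genes are near-identical copies that can share reads, and the reporter in these cells is itself an H2B fusion, so their counts are uncertain. The other 2 named genes were Kif26b and Bcl6, a transcriptional repressor active in cortical neurogenesis, at -0.92 ± 0.21 (adjusted p = 0.0206). The calls of Bcl6 and Hist1h2bc were lost in 5 and 4 of 18 alternatives and those of the other 5 H2B genes in 1 each.

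**Figure D3:**
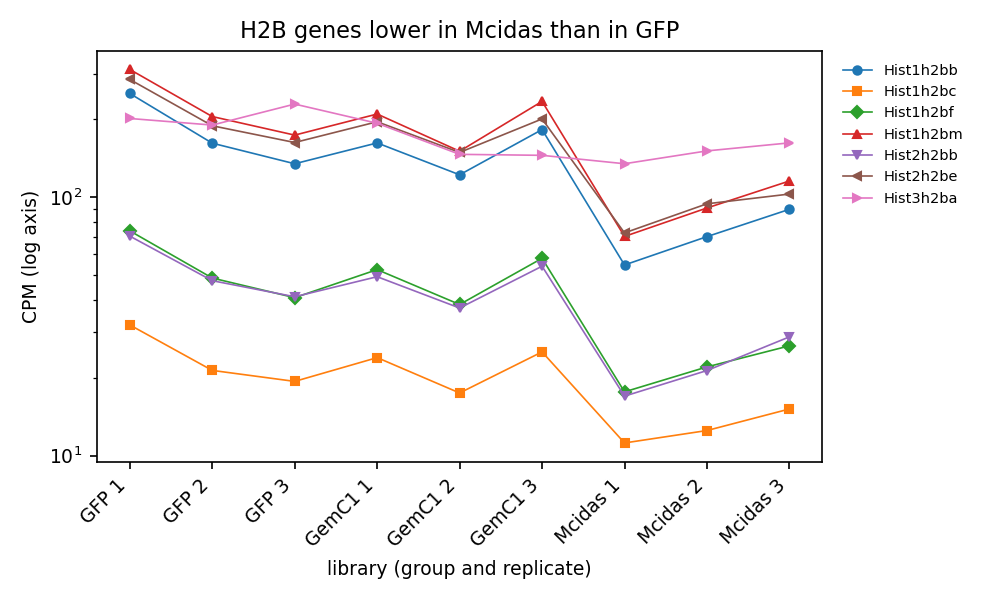
CPM on a log axis of the 7 H2B genes called lower in Mcidas than in GFP, in each of the 9 libraries, with lines joining the values of a gene. Hist1h2bb runs from 54.6 CPM in Mcidas replicate 1 to 251 CPM in GFP replicate 1, and 6 of the genes keep nearly the same ratios over the libraries while Hist3h2ba follows a course of its own.

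The calls of the 2 factors against GFP overlapped. Of the genes higher in each comparison, 600 were higher in both, where independent lists of these sizes would share 30.4. Simulations of unchanged groups called too few genes to give a number for lists of these sizes. Lower in both were 7 genes, against 0.85 for independent lists, and the shared GFP libraries alone may raise this number. They were Asic1, Nvl, Gipr, Adamts2, Tenm4, Plekhf2 and Plcb1, of which only Adamts2 falls under the rule for named genes. Fosb was called in opposite directions. Across the genes tested, which are not independent replicates, the fold changes had a Pearson r of 0.839, where the simulations gave 0.485 on average from the shared GFP libraries. The covariance was 0.70 against 0.096 simulated. Part of the overlap may not be separable from the shared controls, which were too few to split. Among the 600 genes, which are not independent replicates either, 498 had the larger log2 fold change in Mcidas, with a median difference of 0.32. The Mcidas libraries were not alike in this. Above the GFP mean, the median motile cilium gene lay 2.85, 4.22 and 4.31 log2 units in Mcidas replicates 1, 2 and 3. In GemC1 replicates 1, 2 and 3 it lay 3.40, 3.27 and 3.42 above, higher than in Mcidas replicate 1. The overlap of lower calls was 1 gene without GFP replicate 2 and 2 without GFP replicate 3, 4 without Mcidas replicate 2, 11 without Mcidas replicate 1, 20 by DESeq2 and 29 without a low-count filter.

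**Figure D4:**
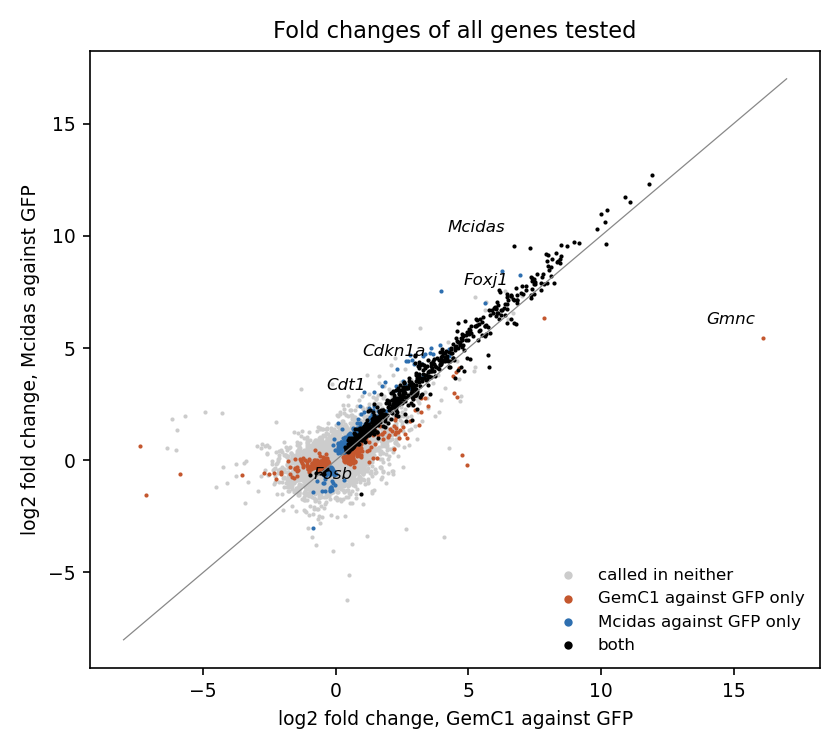
Log2 fold change of each tested gene in Mcidas against GFP (vertical) and in GemC1 against GFP (horizontal), coloured by the comparison in which it was called, with the line of equal change. The 600 genes higher in both lie along and mostly above the line, and values of genes at 0 in GFP, such as Gmnc, depend on the prior count.

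GemC1 against Mcidas compared the groups of the 2 factors directly, and 10 genes were called. If the year code of the files marks a batch, its effect here and on the lists below cannot be told apart from that of the factor. Higher in GemC1 were Gmnc, Fosb, an immediate early transcription factor, by 2.43 ± 0.26 on the log2 scale (SE, adjusted p = 0.00277), and Gm10800, named after its values were seen, by 5.15 ± 0.55. Lower in GemC1 were Mcidas at -2.83 ± 0.14, Cdt1 at -1.06 ± 0.14 (adjusted p = 0.0234), the GABA receptor subunit gene Gabra2 at -1.25 ± 0.19, the neurofilament gene Ina at -0.65 ± 0.10, and St6gal2, Ttc9 and Zfp708. Cdt1 was at 25.3 ± 6.12 CPM in GFP, 68.5 ± 3.40 in GemC1 and 143.3 ± 11.2 in Mcidas. Foxj1 had -0.32 ± 0.24 (adjusted p = 0.613), Cdkn1a -0.29 ± 0.21 (adjusted p = 0.608) and Deup1 -0.84 ± 0.34 (adjusted p = 0.329). An unadjusted p under 0.05 was found for 2551 genes. DESeq2 called 195 higher and 304 lower, and edgeR without a low-count filter 66 and 129, so the number of called genes depended on the tool and the filter. The calls of Cdt1, Gabra2, Ina, St6gal2, Ttc9 and Zfp708 were lost in 6, 11, 13, 4, 12 and 10 of 18 alternatives. The lower calls numbered 1 without Mcidas replicate 2, 3 without GemC1 replicate 2 or any of the GFP replicates, and 4 without GemC1 replicate 3. The higher calls numbered 5 without GemC1 replicate 1 or Mcidas replicate 3.

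By camera, 15 lists differed between GemC1 and Mcidas, and with an estimated correlation none did (lowest adjusted p = 0.22), nor by fry (lowest adjusted p = 0.0995). Higher in GemC1 were the ribosomal protein (median 0.21), immediate early (0.41), interferon (0.73), microglia (0.89), radial glia (0.20), astrocyte (0.24), intermediate progenitor (0.14), S phase (0.09), G2/M (0.08) and Wnt, Bmp and Shh target (0.10) lists. Lower were the motile cilium (-0.50), multiciliated transcription (-0.32), centriole (-0.11), primary cilium (-0.14) and excitatory neuron (-0.15) lists. Among members of these lists only Fosb, Cdt1 and Ina were called over all genes tested. Adjusted over the list alone, 16 of 52 ribosomal protein genes and 12 of 31 immediate early genes were higher, and 9 of 50 excitatory neuron genes were lower. On that basis 7 radial glia genes were higher and 2 lower, 2 S phase genes higher and 3 lower, 1 primary cilium gene higher and 5 lower, 3 astrocyte genes and 1 intermediate progenitor gene higher, and none in the other called lists. Immediate early genes such as Fos, at 1.62 ± 0.29 (SE, adjusted p = 0.118), and Egr1, at 0.96 ± 0.17 (adjusted p = 0.109), missed the threshold. Without Mcidas replicate 3 all 4 cilium and centriole lists lost their camera calls, with adjusted p of 0.121 for motile cilium, 0.163 for primary cilium, 0.299 for multiciliated transcription and 0.264 for centriole genes, and so did the S phase and the Wnt, Bmp and Shh target lists (0.121 and 0.112). Of 16 alternatives, the multiciliated transcription call was lost in 4, the centriole and S phase calls in 3 each, the Wnt, Bmp and Shh target call in 5, the G2/M call in 2 and the intermediate progenitor call in 1. Without Mcidas replicate 1 the G2/M list lost its call and its direction (adjusted p = 0.715).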

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

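The GC correction was chosen after the data had been seen. No named gene changed sign while called in any alternative, and 1 list with a call changed direction, G2/M phase in GemC1 against Mcidas without Mcidas replicate 1 (adjusted p = 0.715). Without Mcidas replicate 3 that list kept its direction (adjusted p = 3.64e-07). The cause of the changes below was not tested, with 1 exception and 1 in part. The 2-fold minimum removes genes by construction. The fit without mitochondrial, globin and transgene counts does so only for the genes left out, so that Gmnc and Mcidas cannot be called. In GemC1 against Mcidas that fit kept 3 of the 7 lower calls. Why genes other than Mcidas lost their calls there was not tested.

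Higher calls for GemC1 against GFP numbered 1159 by DESeq2. Lower calls there were 658 by DESeq2, 557 without a low-count filter and 40 at 2-fold. Lower calls for Mcidas against GFP were 112, 123 and 16 in that order. For GemC1 against Mcidas, DESeq2 called 195 higher and 304 lower, and the fit without a low-count filter 66 and 129. Lower calls there were 4 at 2-fold, 3 without mitochondrial, globin and transgene counts, and 2 with only the groups compared. Genes lower in both numbered 20 by DESeq2, 29 without a low-count filter and 0 at 2-fold. DESeq2 kept 755 of the 756 higher and all 259 lower genes of GemC1 against GFP. With an estimated correlation, 2 lists were higher in GemC1 than in GFP and 0 lower, 0 were lower in Mcidas than in GFP, and 0 differed either way between GemC1 and Mcidas. By fry, 9 lists were higher and 1 lower in GemC1 than in GFP. These included cyclin-dependent kinase inhibitors (fry adjusted p = 0.0475), which camera did not call. Camera calls there that fry did not share were S phase, radial glia, immediate early and interferon (fry adjusted p = 0.0804, 0.119, 0.0662 and 0.405). In Mcidas against GFP fry called 6 lists higher and 0 lower, and 0 differed between the factors. Lists lower in GemC1 than in GFP were 2 without a low-count filter and 2 with only the groups compared.

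Leaving out each library in turn gave 443 to 877 higher and 32 to 267 lower genes for GemC1 against GFP, 557 to 951 and 29 to 99 for Mcidas against GFP, and 3 to 5 and 1 to 8 for GemC1 against Mcidas. Genes higher in both ran from 407 to 702 and lower in both from 1 to 11. Lists higher and lower ran from 10 to 14 and 1 to 2, from 7 to 9 and 2 to 6, and from 8 to 10 and 3 to 6 in the 3 comparisons.

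Samples with the same replicate number did not visibly deviate together (correlations from -0.074 to 0.046). Samples with different numbers had -0.077 to 0.118. Pairing by number was thus not seen, though a small shared effect is not excluded. With the replicate block, 147 genes were lower in GemC1 than in GFP, 3 were lower in GemC1 than in Mcidas and 4 were lower in both, while higher calls were 623, 666 and 3.

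Over named genes and alternatives, 3802 outcomes were the same, 217 calls were lost and 81 gained. For the gene lists, with the estimated correlation and fry included, 1480 outcomes were the same, 92 calls were lost and 44 gained. A list not called in the main fit may thus be called in some alternatives. At this depth and with 3 libraries per group, simulated 1.5-fold changes were mostly missed, so an uncalled gene is not shown to be unchanged.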

Other observations

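The tests of the H2B and microglia patterns were chosen after their values had been seen. The GC test was written before its result but after the GC trend had been seen.

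Next to Mcidas on chromosome 13 lie Ccno and Cdc20b, which also serve centriole amplification, and the genes of this stretch were looked up after the results were seen. In GemC1 against GFP, Ccno (112987802 to 112990777) rose by 4.79 ± 0.25 (SE), Mcidas (112993845 to 113000394) by 6.71 ± 0.21 and Cdc20b (113035111 to 113091195) by 6.37 ± 0.42 on the log2 scale. Dhx29, upstream of Ccno, had -0.19 ± 0.12 (edgeR adjusted p = 0.428), Mtrex -0.11 ± 0.07 (adjusted p = 0.394) and Gpx8, which lies inside the span of Cdc20b on the other strand, 0.81 ± 0.23 (adjusted p = 0.0627). In Mcidas against GFP, Ccno rose by 5.12 ± 0.25 and Cdc20b by 6.95 ± 0.43, while Dhx29 had -0.01 ± 0.12 (adjusted p = 0.989) and Gpx8 0.17 ± 0.23 (adjusted p = 0.866).

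Other genes outside the cilium lists, named after their values were seen, rose with both factors. Igf2 had a log2 fold change of 4.72 ± 0.79 (SE) in GemC1 and 4.14 ± 0.79 in Mcidas. C1ql1 had 2.28 ± 0.34 and 2.23 ± 0.34. Clic6, a choroid plexus chloride channel gene, had 5.68 ± 0.91 and 5.63 ± 0.91. The choroid plexus and hem list was not called in either comparison (camera adjusted p = 0.278 and 0.084). In each, 2 of its 10 tested members were called higher and 0 lower. Gm10800, an unnamed gene model, was at 11.7 ± 6.79 CPM in GemC1, 0.32 ± 0.17 in Mcidas and 0.37 ± 0.24 in GFP.

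Xist was expressed in all 9 libraries, from 103.2 CPM in Mcidas replicate 3 to 365.8 CPM in GemC1 replicate 2, and so was the Y-linked Ddx3y, from 5.79 CPM in GemC1 replicate 2 to 55.9 CPM in Mcidas replicate 3.

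The first pattern concerns the H2B genes called lower in Mcidas than in GFP. Of 12 tested, 7 were called, with a median log2 fold change of -1.25. For a lower share of cells in S phase, the other 23 core histone genes tested had a median of -0.38 (95% bootstrap interval over genes -0.53 to 0.01). The S phase list had -0.04 (-0.12 to 0.04). Both intervals lay above -0.63, the limit set for the test. That limit came from H2B genes picked for being called lower, and resampling genes leaves out the spread between libraries. The test therefore cannot decide on S phase, which stays open, although the S phase list itself showed no clear fall. For the 6 called genes other than Hist3h2ba, reads of the H2B-GFP reporter counted on mouse H2B genes stay open: the called genes had a median pairwise correlation of 0.992 over the 9 libraries and 0.979 within groups, but near-identical genes that share reads could give this under any cause. For Hist3h2ba the correlation with the others was 0.598, which argues against reporter reads as the whole cause of its course. A part from the reporter stays open, since reads of its own RNA could lower that correlation. A biological effect of Mcidas on H2B genes stays open and was not tested.

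The second pattern is the rise of microglia and macrophage markers in GemC1. All 24 markers had a positive log2 fold change, and their median pairwise correlation was 0.71 over the 9 libraries, in part through the rise itself, and 0.477 within groups, so a larger share of microglia among the sorted cells may be an explanation, although the sort for GFP would remove cells without the plasmid. The most abundant markers were Coro1a, at 41.8 ± 5.33 CPM in GemC1 and 35.6 ± 6.36 in GFP, and Csf1r, at 33.0 ± 8.95 and 20.2 ± 2.09, and 9 of the 24 were over 1 CPM in GFP. For carry-over of all non-neural cells alike, the pooled endothelial, pericyte and erythroid markers had a median of 0.026 (95% bootstrap interval -0.57 to 0.22). This lay below 1.10, the limit set for the test, so the markers tested did not rise alike within these libraries. That interval resampled the markers and leaves out the spread between libraries. Only 12 of 26 endothelial, 11 of 20 pericyte and 11 of 20 erythroid markers passed the low-count filter. Whether neural cells also express these was not tested. The meningeal list, left out of the pool, had a median of 0.27. The test therefore cannot exclude such carry-over. An effect of GemC1 itself stays open, as untested. The rise was not confined to GemC1. In Mcidas against GFP 23 of the 24 markers were positive, with a median of 1.26. Relative to the GFP mean, the median marker lay at 2.639, 1.84 and 2.406 log2 units in GemC1 replicates 1, 2 and 3. It lay at 0.462, 1.89 and 1.179 in the Mcidas replicates and at 0.44, 0.369 and -0.785 in the GFP replicates.

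The third pattern is the set of 259 genes lower in GemC1 than in GFP. Their median GC content was 44.2% against 49.1% over all genes tested, and fold changes correlated with GC content across genes (Spearman rho 0.24), which are not independent replicates. With each library's GC trend removed, rho was 0.04, 149 of the 259 were still called lower and their median log2 fold change went from -0.51 to -0.46. This argues against the GC trend as the whole cause, while whether the trend had a part in the rest, which lost their calls, stays open. The dependence of the lower calls on single GFP libraries, given in the report, was not explained by this test.

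For each comparison the 6 libraries allow only 10 splits into 3 and 3, too few for a share under 0.05. The real split called 1015 genes for GemC1 against GFP, 852 for Mcidas against GFP and 10 for GemC1 against Mcidas, and the highest of the other splits called 0 in each. In each comparison 1 split, the real one, gave as many. Every other split puts libraries of both groups on each side, so a difference between the groups adds to the spread. Few calls were therefore likely in those splits beforehand, and their 0 calls lend the real split no support.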
